A study of Mus musculus with 28 samples.

How the data were processed

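Total RNA from 28 mouse samples was measured on Illumina MouseRef-8 v2 bead arrays, 1 array per sample. Per the labels, RNA was extracted with Trizol, amplified with the Illumina TotalPrep kit and labelled with biotin. Per the series design text, each organ sample held dissected domains of 10 to 12 pooled embryos, sorted by flow cytometry for endoderm, in 3 biological replicates. The labels give 4 pancreas samples, and all 4 were used. How the ectoderm and mesoderm samples were isolated is not given in the sources used here. Groups were read from the sample titles alone: endoderm, ectoderm and mesoderm at E8.25, and esophagus, lung, stomach, liver, pancreas and intestine at E11.5.

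The values used are the deposited probe intensities of the series matrix, 25697 probes on 28 arrays with none missing. The submitters' processing notes name BeadStudio, without a version or its role. Normalization, background subtraction and filters are not given in the sources used here. From the values, the deposited intensities are linear, are not centred per gene and have close upper quartiles but different background levels, and 7 arrays hold values below 0. Most values below 0 lay on pancreas 3, with 11861, intestine 3, with 7931, and liver 3, with 1631. Which scaling and background steps made the deposited intensities stays unknown. The median deposited intensity was 41.1, 36.5 and 39.8 in endoderm, 43.8, 41.8 and 41.3 in ectoderm, 35.4, 32.2 and 35.7 in mesoderm, 32.3, 32.0 and 27.6 in esophagus, 30.2, 37.2 and 34.1 in lung, 27.9, 32.9 and 36.4 in stomach, 32.5, 30.5 and 22.9 in liver, 31.5, 27.6, 10.7 and 25.7 in pancreas, and 33.0, 36.1 and 23.2 in intestine, in replicate order.

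A further deposited table, by its name neither normalized nor background-subtracted, has 112 columns, 4 measures for each of 28 arrays, including detection p-values. Its columns carry array identifiers that no sample label gives, so no column could be assigned to a sample, and it was not used here. The plan had been background correction with control probes or detection p-values and a filter on detection p-values. Without that table the written fallback became the main analysis: normexp background correction without controls (offset 50), quantile normalization over the 28 arrays and log2. Variants written in advance that use the series matrix values or normexp without controls are therefore the main analysis itself.

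The substitute for detection p-values was chosen after the files were seen. Sensory receptor genes (olfactory, vomeronasal, trace amine and taste receptors) were taken as probes without signal in these tissues, 1357 probes. A probe counted as detected on an array when it lay above the 99th percentile of these probes there. Of the 25697 probes, 23978 carried 1 gene symbol, 0 carried several and 1719 carried none. The 23978 probes gave 16593 symbols. For each symbol the probe with the highest mean was kept, and the gene was tested if this probe was detected on every array of at least 1 group. This left 9650 genes tested and 6943 symbols not tested, among them Alb, Epcam and Kdr. Symbols were looked up by gene identifier in a mouse gene table for 23962 probes, and 0 changed.

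Each gene was fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0): 1 linear model with the 9 group means, moderated by eBayes, without covariates. The labels do not say that a replicate number pairs samples. In the values, arrays of the same number deviated together for pancreas and intestine (r = 0.667, 0.560 and 0.564) and for ectoderm with both other layers (lowest r = 0.264, 6 pairs), so these comparisons were treated as paired in the splits of the arrays. Pancreas and intestine arrays of different numbers correlated as well, such as pancreas 1 with intestine 2 (0.552) and pancreas 4 with intestine 3 (0.523). Others went the other way, down to -0.743 for pancreas 1 with intestine 3. The replicate number need therefore not be what these arrays share. Organs set against the mean of the others were not treated as paired. The 12 comparisons are each E8.25 layer against the mean of the other 2, each E11.5 organ against the mean of the other 5, the mean of the 6 organs against E8.25 endoderm, lung against esophagus, and pancreas against intestine. P-values were adjusted by Benjamini and Hochberg within each comparison. A call needs an adjusted p under 0.05 and a log2 fold change of at least 1 in size. Where a group on the dim side was undetected on all its arrays, the fold change is given as a bound computed from the detection threshold. A gene restricted to an organ was called higher there in each of the 5 pairwise comparisons. Arrays, not genes, are the replicates, and with 3 or 4 arrays per group their number limits the precision. The comparisons of the organs share arrays, so their results are not independent of each other.

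The comparisons, tests, gene lists, alternatives and rule for named genes were written before the data were examined. The 36 lists cover germ layer, organ and cell type markers, signalling pathways, Hox groups, metabolism, cell cycle, imprinted growth genes and immediate early genes. Each list with at least 3 tested members was tested with camera (inter-gene correlation 0.01), adjusted over all lists and comparisons, and again with an estimated correlation. Of 432 list tests, the 284 assigned to a comparison in advance are reported. Members were also adjusted over the list alone. The text names, per comparison, up to 10 genes with the largest rise and 5 with the largest fall among called genes whose every target array lay on the same side of the reference (15 and 15 for the stage comparison, 5 and 5 for the pairs), ranked by bound where only a bound is known. It also names up to 4 called members of each list, and up to 4 members not called of an organ's own list. Predicted or unnamed symbols were passed over.

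The script was tested on simulated log2 values with each gene's mean over all arrays, its spread within groups and 200 of 9650 genes changed. Noise was independent between arrays, without deviations shared by arrays, and the changes were added after normalization. The simulation therefore covers the fit and the calls, not background correction, normalization or shared deviations. It recovered 93% to 100% of changes of 1.5 on the log2 scale, all changes of 3, and made 0 to 3 false calls per comparison. Alternatives covered background correction, normalization, detection filters, probe choice, the arrays included, array weights, the replicate number as a block, the variance prior and the list test. Alternatives added after the files were seen were neqc with receptor probes as negative controls (offset 16), detection at the 95th percentile, leaving out pairs of arrays, and the class of highest deposited intensity, under or over 20000, as a block or within 1 class.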

Results

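The series profiled gene expression in endodermal organs of the mouse embryo at E11.5 and in the germ layers at E8.25. RNA was amplified, labelled with biotin and hybridised to Illumina MouseRef-8 v2 bead arrays, 1 array per sample. The 28 arrays fall into 9 groups: definitive endoderm, ectoderm and mesoderm of embryos with 4 to 6 somites at E8.25, with 3 arrays each, and the esophagus, lung, stomach, liver and intestine domains at E11.5, with 3 arrays each, and the pancreas domain, with 4. Each organ sample was endoderm isolated by flow cytometry from the dissected domains of 10 to 12 pooled embryos. A p-value therefore measures the spread between these samples, and the number of arrays limits the precision. Differences are given as log2 fold changes ± standard error from a single limma model of the 28 arrays, which tested 9650 genes. A gene was called higher or lower at an adjusted p under 0.05 and a change of at least 2-fold. Where the dimmer side was not above background on any array of a group, the size of a called gene is a lower bound, written as "at least", and genes not called are given with their fitted value. The bound allows for background, not for spread between arrays. An organ is compared with the mean of the other 5, which organs without a transcript pull down, so a higher gene need not be highest in that organ. Likewise, an organ or layer with a high level pulls the mean up. A gene called lower therefore need not be lowest in the group compared, as with liver genes in the other organs.

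Arrays of a group resembled each other. Within groups, Pearson's r across the tested genes, which are not independent replicates, lay between 0.946 and 0.995, and between groups it lay between 0.796 and 0.980. Of the 28 arrays, 27 were most similar to an array of their own group. The exception was lung 1, nearly a tie: r was 0.9660 with stomach 1 and 0.9658 with its closest lung array. The leading principal components held 25.9%, 23.2%, 12.6% and 7.72% of the variance. Spread between replicates was smallest in ectoderm, with a median SD of 0.098 on the log2 scale, and largest in pancreas, at 0.232. Pancreas 3 and intestine 3 had fewer probes above their receptor threshold, 7070 and 9663, than the other arrays, which had 10831 to 12893. A further 8 arrays, mesoderm 1 to 3, liver 1 to 3, lung 1 and stomach 1, had no deposited intensity over 20000, whereas the other 20 did. Mesoderm and liver lay wholly in the class of 8 arrays, so values with this class as a block, or within 1 class, are given with each comparison.

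**Figure D1:**
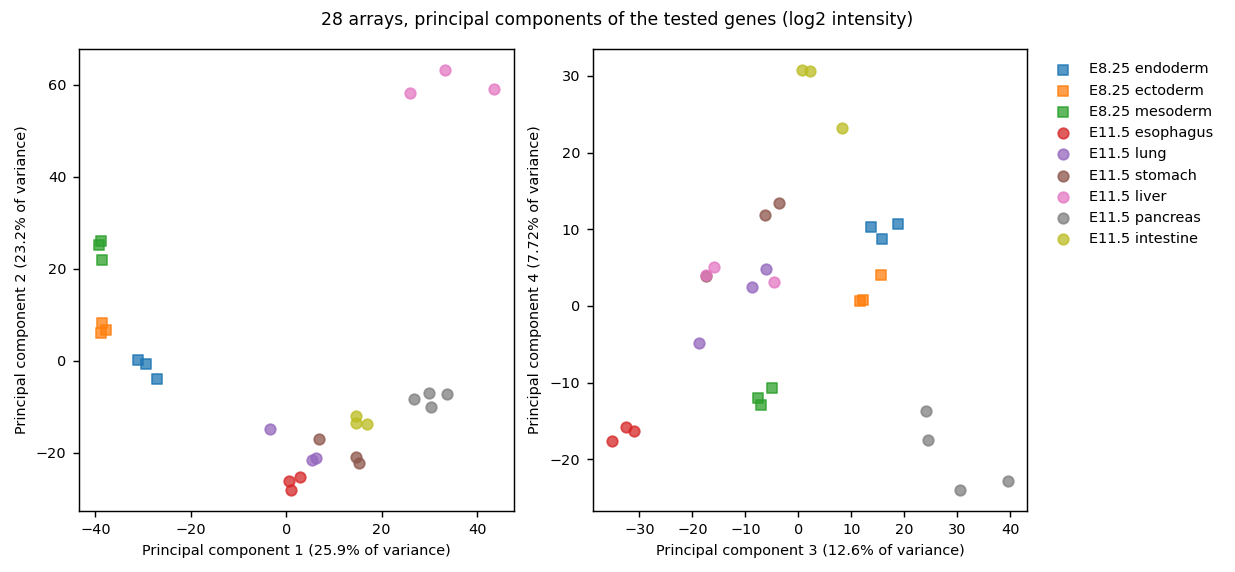
Scores of the 28 arrays on principal components 1 and 2 (left, 25.9% and 23.2% of the variance) and 3 and 4 (right, 12.6% and 7.72%), computed from the normalized log2 values of 9650 genes. Each point is 1 array, coloured by group, with squares for E8.25 and circles for E11.5.

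The lists of marker and pathway genes were fixed before the data were examined. For each list the text gives the members called, the median log2 fold change, the same median with bounded genes set at their bound, and camera's adjusted p. Members are counted among those tested, and members without detection on all arrays of any group are left out. Of the members on the array, 9 of 16 were tested for the stomach list and 11 of 19 for the intestine list. Of 284 list results reported, 129 were past the threshold, and 68 of these were not past it with an estimated correlation. In 39 results the median or mean had another sign than the test, and 0 of the 39 were past the threshold. Counts adjusted over the list alone equalled the counts over all genes tested except in 4 results, which are named where they occur.

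**Figure D2:**
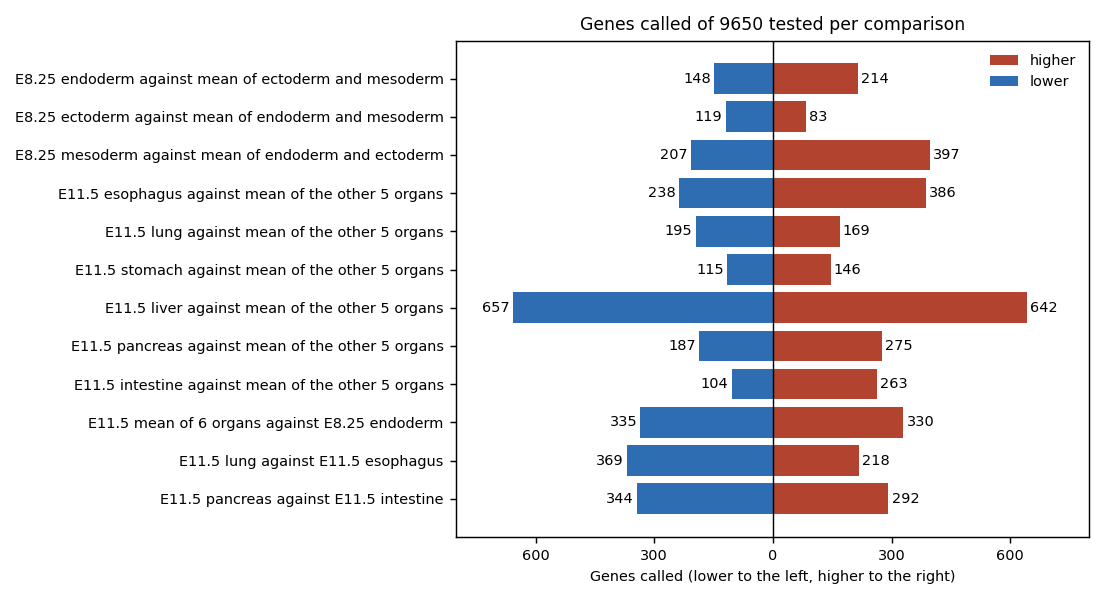
Number of genes called higher (bars to the right) and lower (bars to the left) in each of the 12 comparisons, of 9650 genes tested. Liver had the most calls against the other organs, 642 higher and 657 lower, and E8.25 ectoderm the fewest among all comparisons, 83 higher and 119 lower.

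Definitive endoderm at E8.25, set against the mean of ectoderm and mesoderm, was marked by genes of its own list and of epithelial junctions. The tight junction gene Cldn6 was higher by 4.48 ± 0.25 (adjusted p = 5.1e-12, n = 3 against 6 arrays), the trypsin inhibitor gene Spink1 by 4.41 ± 0.28, and the epithelial splicing regulator Esrp1 by 4.23 ± 0.25. The transmembrane protease gene Tmprss2 was at least 17.0-fold higher, Cldn4 at least 10.9-fold, the pioneer factor gene Foxa1 at least 7.81-fold and the peptide hormone gene Pyy at least 8.58-fold. Of 18 tested members of the definitive endoderm list, 15 were higher and 0 lower (median 2.17, 2.08 with bounds, adjusted p = 2.9e-24). The epithelial junction list had 12 of 19 members higher, among them Cldn6, Esrp1, Cldn4 and the transcription factor gene Grhl2, at least 6.81-fold higher (median 1.34, 1.09 with bounds, adjusted p = 2.0e-19).

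Genes usually used as markers of surface ectoderm were also higher in endoderm than in the mean of the other layers. In the list of surface ectoderm and neural crest, 8 of 10 members were higher and 1 lower, including Tfap2c at 2.26 ± 0.13, Tfap2a at 2.25 ± 0.12 and Dlx3 at 1.99 ± 0.13 (median 1.74, 1.60 with bounds, adjusted p = 1.1e-10). Yolk sac and visceral endoderm genes had 3 of 14 members higher, the thyroxine carrier Ttr by 3.28 ± 0.33, Apoa1 by 1.42 ± 0.19 and Apom by 1.32 ± 0.28 (median 0.41, 0.23 with bounds, adjusted p = 0.00814, adjusted p = 0.115 with an estimated correlation). Notochord genes had 2 of 6 members higher, with Shh at least 3.30-fold higher (median 0.82, 0.71 with bounds, adjusted p = 0.0393, adjusted p = 0.0900 with an estimated correlation). Genes of the mesoderm derivatives were lower. Of the paraxial mesoderm list, 6 of 10 members were lower, with Foxc2 at least 4.71-fold lower (median -1.59, -1.59 with bounds, adjusted p = 1.1e-13). Of the cardiac and lateral mesoderm list 5 of 18 were lower and 1 higher, with Myl4 at -2.93 ± 0.21 and Actc1 at -2.77 ± 0.21 (median -0.42, -0.41 with bounds, adjusted p = 6.7e-07). The endothelium list had 8 of 14 members lower, Etv2 at -2.25 ± 0.15 (median -1.31, -0.99 with bounds, adjusted p = 1.8e-17). The erythroid list had 5 of 10 lower, or 6 adjusted over the list alone, with the embryonic globin Hbb-bh1 at least 15.5-fold lower (median -1.19, -1.06 with bounds, adjusted p = 4.1e-05, adjusted p = 0.199 with an estimated correlation). Neural genes went both ways, the forebrain factor Otx2 at 1.38 ± 0.17, with 1 of 15 members higher and 2 lower (median -0.31, -0.31 with bounds, adjusted p = 0.0471, adjusted p = 0.531 with an estimated correlation). The cell cycle list had 0 of 21 members called (a median of -0.01, -0.01 with bounds, a mean of 0.00 and a test pointing higher, adjusted p = 0.842). In all, 214 genes were higher and 148 lower. Against ectoderm alone, where all 6 arrays lie in 1 intensity class, 273 genes were called with all arrays in the model and 274 with arrays of that class only.

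Ectoderm at E8.25 was set apart from the mean of endoderm and mesoderm by regional patterning genes of the neural plate. The homeobox gene Otx1 was higher by 2.47 ± 0.33 (adjusted p = 1.1e-05, n = 3 against 6), the hindbrain segment gene Egr2 by 2.33 ± 0.30, Sox21 by 2.23 ± 0.40 and Rfx4 by 2.17 ± 0.31. The sizes for Sox21 and Otx1 depend on mesoderm 2. On mesoderm 1 to 3, Sox21 stood at 8.17, 10.75 and 7.30 and Otx1 at 6.89, 8.65 and 7.02 (log2 intensity). Without mesoderm 2 the comparison called 236 genes, and the cause of this array's levels was not tested. The midbrain and hindbrain genes En2 and En1 were higher by 1.95 ± 0.29 and 1.81 ± 0.10, and the Wnt ligands Wnt3a and Wnt8a by 2.14 ± 0.24 and 1.80 ± 0.29. The neural ectoderm list had 5 of 15 members higher and 0 lower (median 0.75, 0.75 with bounds, adjusted p = 1.8e-12). Surface ectoderm and neural crest genes, by contrast, had 0 of 10 members called in either direction (median -0.38, -0.38 with bounds, adjusted p = 0.0492, adjusted p = 0.303 with an estimated correlation, adjusted p = 0.0542 with the replicate number as a block).

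Genes of heart, vessels and gut were lower in ectoderm. The ventricular myosin light chain gene Myl3 stood at -2.46 ± 0.17, Isl1 at -2.45 ± 0.19, Gata6 at -2.41 ± 0.13 and the endoderm factor Sox17 was at least 4.47-fold lower. Of the cardiac and lateral mesoderm list 7 of 18 members were lower (median -0.88, -0.78 with bounds, adjusted p = 2.9e-24). So were 8 of 14 of the endothelium list (median -1.03, -0.92 with bounds, adjusted p = 3.6e-21) and 6 of 18 of the definitive endoderm list (median -0.62, -0.62 with bounds, adjusted p = 1.1e-09). The epithelial junction list had 3 of 19 members lower, Krt18 at -1.98 ± 0.22 and Krt8 at -1.75 ± 0.17 (median -0.36, -0.25 with bounds, adjusted p = 6.4e-07). The erythroid list had 2 of 10 members lower (median -0.92, -0.86 with bounds, adjusted p = 4.4e-04, adjusted p = 0.278 with an estimated correlation), Hba-x at -1.69 ± 0.54 and Hbb-bh1 at -1.62 ± 0.38, neither of which was called in every fit that left out 1 array. Neither globin was lower in ectoderm than in endoderm, and mesoderm raised the reference mean. Hbb-bh1 stood at 6.88, 8.59 and 7.80 on ectoderm 1 to 3 and at 5.94, 6.12 and 5.85 on endoderm 1 to 3. On mesoderm 1 to 3 it stood at 11.51, 13.52 and 13.34 (log2 intensity). The paraxial mesoderm list had 1 of 10 members higher and 0 lower, Tbx6, at 1.21 ± 0.25, which was not called without ectoderm 3, while the test put the list lower (median -0.13, -0.13 with bounds, adjusted p = 0.0293, adjusted p = 0.303 with an estimated correlation). Notochord genes had 1 of 6 members higher, Foxd4, at 2.19 ± 0.34 (median 0.29, 0.24 with bounds, adjusted p = 0.0168, adjusted p = 0.0515 with an estimated correlation). The immediate early list, which holds genes induced by stress and dissociation, had 1 of 14 higher, Egr2 (median -0.23, -0.23 with bounds, adjusted p = 0.0353, adjusted p = 0.390 with an estimated correlation). The comparison called 83 genes higher and 119 lower, or 93 and 147 with the intensity class as a block, and within 1 class only ectoderm and endoderm can be compared.

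Mesoderm at E8.25 carried the transcripts of blood, heart and vessels. The embryonic globin Hbb-bh1 was at least 53.9-fold higher than in the mean of endoderm and ectoderm (adjusted p = 2.3e-11, n = 3 against 6), Hba-x at least 20.9-fold and Hbb-y at least 10.4-fold. The sarcomere genes Actc1, Myl4 and Myl7 were higher by 4.78 ± 0.21, 4.36 ± 0.21 and 4.25 ± 0.14, and the endothelial genes Esam, Plvap and Tek by 3.46 ± 0.21, 3.22 ± 0.17 and 3.21 ± 0.12. The endothelium list had 13 of 14 members higher (median 2.40, 2.18 with bounds, adjusted p = 1.9e-23) and the cardiac and lateral mesoderm list 9 of 18 (median 1.15, 1.15 with bounds, adjusted p = 3.2e-21). The paraxial mesoderm list had 7 of 10 higher, with Foxc2 at least 9.07-fold and Tcf15 at least 4.82-fold higher (median 1.49, 1.48 with bounds, adjusted p = 6.6e-12). Of the erythroid list 8 of 10 were higher (median 2.11, 2.01 with bounds, adjusted p = 6.0e-07, adjusted p = 0.115 with an estimated correlation). Globin levels differed between the replicate mesoderm samples, so the size of these differences depends on single arrays: on mesoderm 1 to 3, Hbb-y stood at 7.19, 12.48 and 9.76 and Hba-x at 8.71, 12.47 and 11.51 (log2 intensity).

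Epithelial genes were lower in mesoderm, Esrp1 at -4.32 ± 0.25 and Cldn6 at -4.05 ± 0.25, and 7 of 19 members of the epithelial junction list were lower (median -0.68, -0.38 with bounds, adjusted p = 1.3e-06). So were 10 of 18 definitive endoderm genes (median -1.34, -1.27 with bounds, adjusted p = 1.5e-06). Also lower were 6 of 10 surface ectoderm and neural crest genes, Tfap2a at -2.71 ± 0.12 (median -1.25, -0.95 with bounds, adjusted p = 5.6e-05), and 4 of 15 neural genes, Otx2 at -2.65 ± 0.17 (median -0.57, -0.57 with bounds, adjusted p = 0.00524, adjusted p = 0.390 with an estimated correlation). Of the notochord list 2 of 6 were lower (median -0.92, -0.70 with bounds, adjusted p = 0.00450). Adjusted over the list alone, each count for mesoderm was the same. The model called 397 genes higher and 207 lower. The share of higher genes depended on the processing: without background correction 651 were higher and 596 lower, with receptor probes as negative controls 641 and 548, and with the intensity class as a block 397 and 412. Pcna and Hmga2, called higher at 1.64 ± 0.48 and 1.36 ± 0.35, stood at -0.98 and -0.42 with that block, and no comparison of mesoderm within 1 class could be made.

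**Figure D3:**
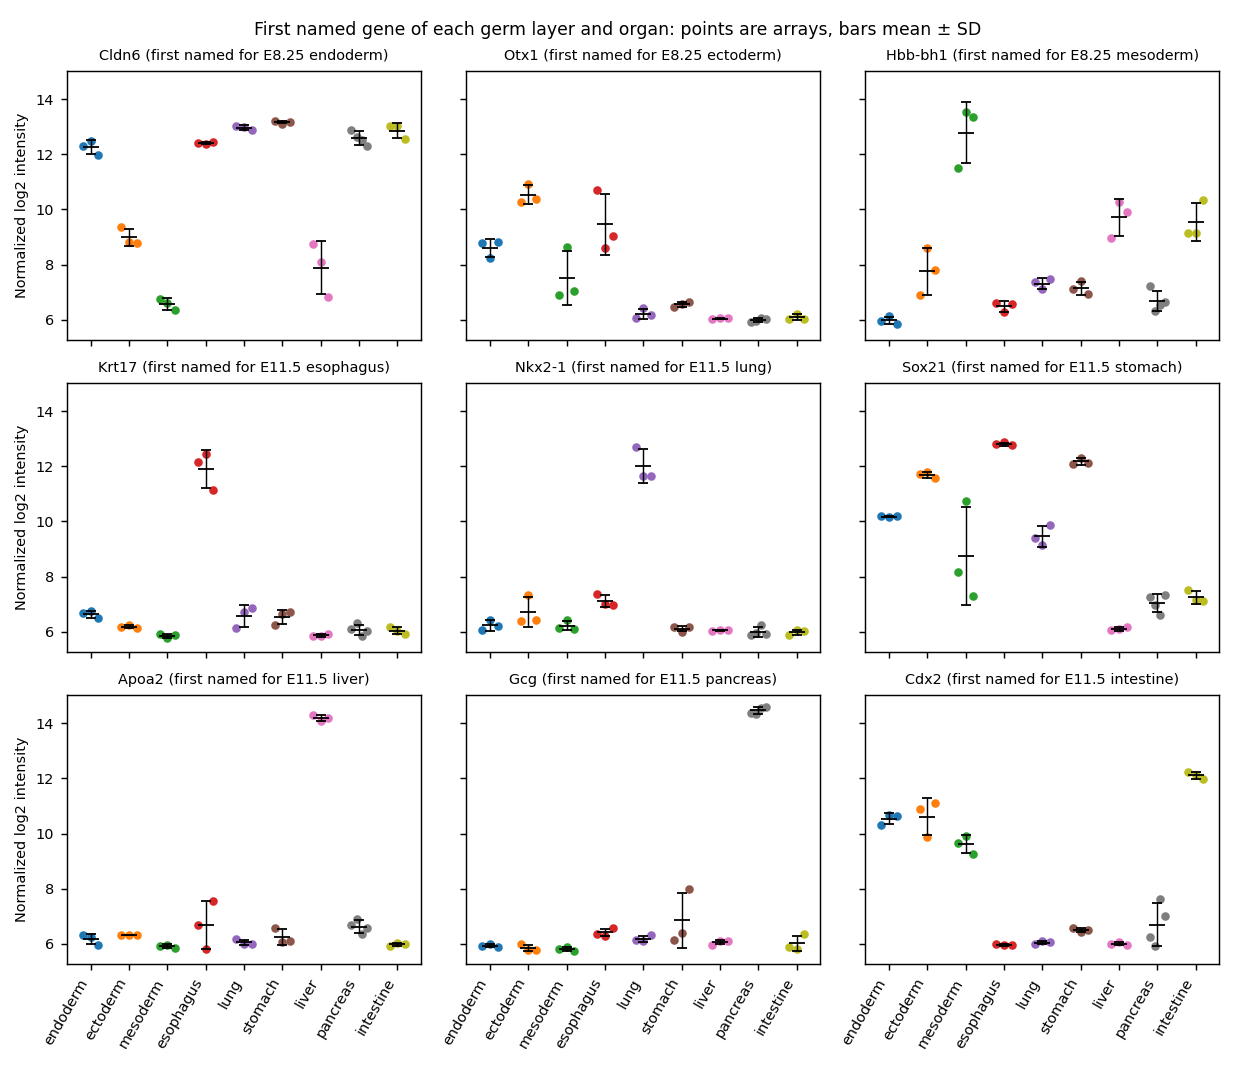
Normalized log2 intensity of 9 genes, the first named gene of each E8.25 layer and E11.5 organ, on each of the 28 arrays. Points are arrays, black marks the group mean with 1 SD (n = 3, pancreas 4).

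Esophageal endoderm at E11.5 was marked by the program of a stratified epithelium. Against the mean of the other 5 organs the keratin genes Krt17 and Krt15 were at least 41.9-fold and at least 45.5-fold higher (adjusted p = 4.3e-17 and 8.5e-17, n = 3 against 16 arrays). Expression of Trp63, the master regulator of stratified epithelia, was at least 39.3-fold higher. The foregut factors Foxe1 and Sox2 were at least 9.88-fold and at least 4.84-fold higher and Sox21 at least 20.4-fold. Of 12 tested members of the esophagus list 11 were higher, also adjusted over the list alone (median 2.34, 2.17 with bounds, adjusted p = 1.1e-18), and the other, Pax9, stood at 0.62 ± 0.07. The stomach list shared this direction, with 5 of 9 members higher, among them Sox21 and Foxq1, the latter by 3.18 ± 0.16 (median 1.98, 1.68 with bounds, adjusted p = 0.0492, adjusted p = 0.102 with an estimated correlation).

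Several signalling and patterning genes were higher in esophagus too. Of the Notch pathway list 5 of 12 members were higher, Nrarp by 2.27 ± 0.13, Hey1 by 1.23 ± 0.11 and the ligand Jag1 at least 2.38-fold (median 0.73, 0.73 with bounds, adjusted p = 6.3e-05). Anterior Hox genes of groups 1 to 4 had 5 of 9 members higher, Hoxb4 by 2.16 ± 0.19 and Hoxa2 by 2.10 ± 0.15 (median 1.62, 1.57 with bounds, adjusted p = 0.00450, adjusted p = 0.177 with an estimated correlation). In groups 5 to 8, 2 of 8 were higher, Hoxc6 at least 12.6-fold and Hoxa5 by 1.89 ± 0.30, and the list had a median of -0.22, 0.00 with bounds, a mean of 0.53 and a test pointing higher, adjusted p = 0.692. Retinoic acid genes moved apart, the receptor Rarb at 1.98 ± 0.24, the enzyme Aldh1a1 at least 3.34-fold higher and the retinol carrier Rbp4 at -2.60 ± 0.28 (median 0.07, 0.07 with bounds, adjusted p = 0.606). Markers of mesenchyme moved with these genes: 4 of 18 were higher and 1 lower, the proteoglycan gene Dcn by 4.28 ± 0.22 and smooth muscle actin Acta2 by 3.28 ± 0.33 (median 0.53, 0.27 with bounds, adjusted p = 8.9e-04, adjusted p = 0.260 with an estimated correlation).

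Liver and pancreas genes were lower in esophagus. The hepatocyte list had 18 of 23 members lower, Ambp at -4.99 ± 0.22, Ttr at -4.54 ± 0.30 and Serpina1b at -4.27 ± 0.20 (median -1.45, -1.34 with bounds, adjusted p = 2.3e-17). The pancreatic endocrine list had 4 of 15 lower (median -0.70, -0.37 with bounds, adjusted p = 5.0e-08) and the intestine list 3 of 11 (median -0.70, -0.52 with bounds, adjusted p = 4.1e-06). Imprinted growth genes had 3 of 11 members lower and 1 higher, Dlk1 at -2.75 ± 0.21 and Peg3 at -2.13 ± 0.31 (median -0.52, -0.52 with bounds, adjusted p = 0.0296, adjusted p = 0.0657 with an estimated correlation). Cholesterol synthesis genes had 0 of 14 called (median -0.49, -0.49 with bounds, adjusted p = 0.0148, adjusted p = 0.278 with an estimated correlation). In total 386 genes were higher and 238 lower. Without liver in the reference 560 genes were called with all arrays and 663 among arrays of the class with intensities over 20000.

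Lung endoderm was set apart by Nkx2-1, the lineage factor of the respiratory epithelium, which was at least 42.4-fold higher than in the mean of the other 5 organs (adjusted p = 4.6e-17, n = 3 against 16). The ligand Wnt7b was at least 24.4-fold higher, the Iroquois factors Irx3 and Irx2 at least 18.4-fold and at least 11.6-fold, Cdh16 at least 9.53-fold and the matrix protein gene Matn4 at least 8.72-fold. Tgfb2 and the carboxylesterase gene Ces1d were higher by 3.24 ± 0.20 and 3.16 ± 0.14. Of 18 tested members of the lung list 10 were higher and 0 lower, also adjusted over the list alone (median 1.55, 1.32 with bounds, adjusted p = 4.7e-16). Members not called included the distal tip factor Sox9 at 0.87 ± 0.11, the surfactant protein Sftpb at 0.77 ± 0.10, Tbx3 at -0.80 ± 0.11 and Etv4 at -0.74 ± 0.26.

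Individual targets of signalling pathways were among the called genes in lung. The FGF target Etv5 was higher by 2.76 ± 0.16, but the FGF response list had 1 of 11 members higher and 1 lower, with a median of -0.18, -0.18 with bounds, a mean of 0.03 and a test pointing lower, adjusted p = 0.831. Bmp4 was at least 6.55-fold higher, with 1 of 9 BMP response genes higher (median 0.08, 0.00 with bounds, adjusted p = 0.900). The Wnt target Sp5 was higher by 2.93 ± 0.22, with 1 of 11 Wnt response genes higher (median 0.18, 0.14 with bounds, adjusted p = 0.0398, adjusted p = 0.217 with an estimated correlation). Shh was at least 2.88-fold higher and Ihh at least 2.50-fold lower among the 7 Hedgehog genes (median 0.25, 0.21 with bounds, adjusted p = 0.0442, adjusted p = 0.0999 with an estimated correlation). Cell cycle genes had 0 of 21 members called, and their test put the list higher (median 0.32, 0.32 with bounds, adjusted p = 0.00152). Immediate early genes had 1 of 14 members higher and 1 lower, or 2 lower adjusted over the list alone (median -0.20, -0.13 with bounds, adjusted p = 0.686). Hepatocyte genes had 14 of 23 members lower, Ambp at -5.19 ± 0.22 (median -1.33, -1.17 with bounds, adjusted p = 3.6e-20). The stomach list had 2 of 9 members higher and 1 lower, with Irx5 and Cldn18 at least 9.16-fold and at least 5.29-fold higher and a median of -0.38, -0.29 with bounds, a mean of 0.37 and a test pointing lower, adjusted p = 0.921. The model called 169 genes higher and 195 lower. Without liver in the reference 296 genes were called with all arrays and 316 within the class of intensities over 20000.

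Stomach endoderm had the fewest genes higher than in each other organ, 19. Sox21 was at least 12.1-fold higher than in the mean of the other 5 organs (adjusted p = 5.5e-08, n = 3 against 16), the membrane protein gene Tspan8 at least 10.4-fold, Id4, an inhibitor of basic helix-loop-helix factors, at least 8.18-fold and the adenylate cyclase gene Adcy8 at least 7.21-fold. The epithelial factor Klf5 was higher by 3.21 ± 0.18 and Plac8 by 2.73 ± 0.23. Sox21 was not highest in stomach: its level was 12.18 ± 0.12 there and 12.81 ± 0.05 in esophagus (log2 intensity, SD, n = 3 each). Of 9 tested members of the stomach list 4 were higher and 0 lower, also adjusted over the list alone (median 0.60, 0.55 with bounds, adjusted p = 8.6e-07), with Sox2 at least 2.40-fold higher. Gastric markers not called were Tff1 at 0.60 ± 0.16, Gata4 at 0.55 ± 0.15, Foxq1 at 0.54 ± 0.16 and Cldn18 at 0.18 ± 0.13.

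Of the epithelial junction list 6 of 19 members were called higher in stomach than in the mean of the other organs, Cldn6 by 1.42 ± 0.22 and Krt18 by 1.39 ± 0.20 (median 0.48, 0.43 with bounds, adjusted p = 2.2e-09). Liver lowers that mean for Cldn6, at 7.89 ± 0.97 against 13.17 ± 0.04 in stomach, 12.97 ± 0.09 in lung and 12.86 ± 0.27 in intestine. Both Hedgehog ligands of the list were higher than in the mean of the other organs, Ihh at least 3.87-fold and Shh at least 2.65-fold (median 0.15, 0.15 with bounds, adjusted p = 0.0406, adjusted p = 0.0922 with an estimated correlation). Shh was detected on 0 arrays of liver and pancreas, and stomach, at 11.20 ± 0.34, had the lowest mean of the other 4 organs. The pancreatic and duodenal factor Pdx1 was at least 2.14-fold higher and Rfx6 at least 2.47-fold. Barx1, a gene of gastric mesenchyme, was at least 2.52-fold higher, while Acta2 stood at -2.29 ± 0.33 among 18 mesenchyme genes, of which 1 was higher and 2 lower (median -0.35, -0.22 with bounds, adjusted p = 0.00480, adjusted p = 0.338 with an estimated correlation). The growth regulator Dlk1 stood at -3.09 ± 0.21 and the digestive enzyme relative Pnliprp1 was at least 4.75-fold lower. Of the hepatocyte list 11 of 23 members were lower and 1 higher (median -0.97, -0.53 with bounds, adjusted p = 7.1e-13). In all 146 genes were higher and 115 lower. Without liver in the reference 190 were called with all arrays and 200 within the class of intensities over 20000.

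Liver endoderm had the most genes called against the other organs, 1299. The apolipoprotein Apoa2 was at least 208-fold higher (adjusted p = 4.6e-20, n = 3 against 16), Apom at least 77.0-fold, transferrin, Trf, at least 76.5-fold, the corticosteroid carrier Serpina6 at least 74.9-fold and the fibrinogen chain Fga at least 58.2-fold. Reln, Apoa1 and Afp were higher by 6.06 ± 0.13, 5.59 ± 0.17 and 5.45 ± 0.26. Of 23 tested members of the hepatocyte list 20 were higher and 0 lower, also adjusted over the list alone (median 3.64, 3.64 with bounds, adjusted p = 1.4e-21). The others were Cebpa at 0.92 ± 0.28, Apoc3 at 0.77 ± 0.07 and Nr1h4 at 0.33 ± 0.10. Urea cycle genes of the hepatocyte metabolism list moved apart, Ass1 at least 7.97-fold higher and Arg1 at -1.01 ± 0.25, a call lost when any of 8 single arrays was left out. The list had 2 of 4 tested members higher and 1 lower (median 1.03, 0.72 with bounds, adjusted p = 0.0271, adjusted p = 0.0718 with an estimated correlation). It has 17 members on the array, so most were not tested. Cholesterol synthesis genes had 3 of 14 members higher, Lss by 1.71 ± 0.14 (median 0.64, 0.64 with bounds, adjusted p = 0.00149, adjusted p = 0.155 with an estimated correlation).

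Blood cell markers moved with the liver genes. The leukocyte list had 7 of 8 members higher, Laptm5 by 3.76 ± 0.27, Coro1a by 2.71 ± 0.15, Mpo at least 4.35-fold and C1qb at least 4.41-fold (median 2.39, 1.97 with bounds, adjusted p = 6.8e-08), and the platelet factor gene Pf4 was at least 38.2-fold higher. The erythroid list had 7 of 10 members higher, Hbb-bh1 by 2.29 ± 0.34 and the red cell factor Klf1 by 1.68 ± 0.15 (median 1.66, 1.58 with bounds, adjusted p = 0.00598, adjusted p = 0.396 with an estimated correlation). The endothelium list had 3 of 14 higher, Plvap at least 2.54-fold (median 0.55, 0.23 with bounds, adjusted p = 0.00231, adjusted p = 0.220 with an estimated correlation). Epithelial genes were lower: Esrp1 at -5.83 ± 0.22, Cldn6 at -4.92 ± 0.22 and 13 of 19 junction genes in all (median -1.45, -1.35 with bounds, adjusted p = 6.4e-09). The Notch list had 5 of 12 members lower, Nrarp at -2.27 ± 0.13 and Notch3 at -2.15 ± 0.15 (median -0.83, -0.66 with bounds, adjusted p = 7.7e-04). The lung list had 9 of 18 members lower and 1 higher, Shh at least 20.2-fold lower (median -0.94, -0.87 with bounds, adjusted p = 6.6e-04). The neuron and neural crest list had 1 of 9 higher, Ednrb, by 1.94 ± 0.17, with a median of -0.14, 0.00 with bounds, a mean of 0.04 and a test pointing lower, adjusted p = 0.909. The model called 642 genes higher and 657 lower, or 427 and 635 with detection required on 14 of the 28 arrays. Against the mean of lung and stomach 1389 genes were called with all arrays and 1420 among the 5 arrays of liver, lung and stomach in the liver's intensity class, of which 1181 are shared. In that class lung and stomach have 1 array each.

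**Figure D4:**
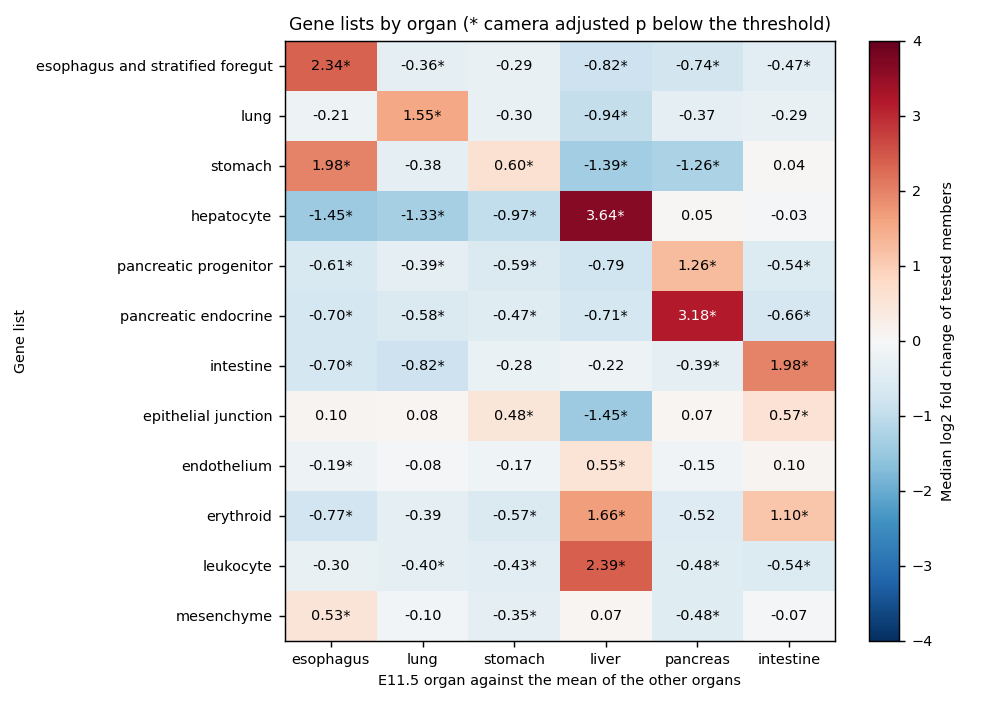
Median log2 fold change of 12 gene lists (rows) in each E11.5 organ against the mean of the other 5 (columns). An asterisk marks an adjusted p from camera under 0.05. The pancreatic endocrine list in pancreas and the hepatocyte list in liver had the highest medians, 3.18 and 3.64.

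Pancreatic endoderm carried endocrine and exocrine progenitor transcripts side by side. The hormone genes Gcg and Pyy were at least 250.1-fold and at least 134-fold higher than in the mean of the other organs (adjusted p = 1.8e-20 and 3.8e-23, n = 4 against 15), and the carboxypeptidase Cpa1 and the colipase Clps at least 74.9-fold and at least 30.2-fold. Transcription factor genes of the pancreas were higher, Nkx2-2 at least 40.7-fold, Nkx6-1 at least 22.5-fold and Ptf1a at least 12.9-fold, and the amino acid transporter gene Slc38a5 by 6.48 ± 0.21. Of 15 tested endocrine genes 14 were higher (median 3.18, 2.92 with bounds, adjusted p = 1.9e-28), and of 16 progenitor genes 8 (median 1.26, 1.18 with bounds, adjusted p = 3.1e-15), the same counts as adjusted over the list alone. Progenitor genes not called were Rbpjl at 0.66 ± 0.18, Gata6 at 0.50 ± 0.10, Foxa2 at 0.36 ± 0.13 and Bhlha15 at 0.33 ± 0.10.

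In pancreas Foxa1, Axl and the corepressor Tle4 were lower, at -3.01 ± 0.27, -2.88 ± 0.10 and -2.84 ± 0.10. Notch genes had 3 of 12 members higher, Nrarp by 2.24 ± 0.12 and Hey1 by 1.92 ± 0.10 (median 0.37, 0.29 with bounds, adjusted p = 2.2e-04). Imprinted growth genes had 4 of 11 members higher, Dlk1 by 3.19 ± 0.18 and Mest by 2.71 ± 0.21 (median 0.26, 0.26 with bounds, adjusted p = 0.0797). Hox genes were lower in groups 1 to 4, with 2 of 9 members called, Hoxb4 at -1.91 ± 0.17 (median -0.72, -0.59 with bounds, adjusted p = 0.00199, adjusted p = 0.143 with an estimated correlation). In groups 5 to 8 there were 3 of 8 lower, Hoxa5 at -1.90 ± 0.26 (median -0.53, -0.28 with bounds, adjusted p = 0.00538, adjusted p = 0.285 with an estimated correlation). The stomach list had 5 of 9 members lower (median -1.26, -0.92 with bounds, adjusted p = 1.2e-05) and the esophagus list 4 of 12 (median -0.74, -0.38 with bounds, adjusted p = 1.2e-06). Some liver genes were higher in pancreas as well, Ttr by 3.59 ± 0.26 and Ambp by 3.20 ± 0.20, with 5 of 23 hepatocyte genes higher and 3 lower (median 0.05, 0.00 with bounds, adjusted p = 0.106). The erythroid list had 1 of 10 members lower, or 3 adjusted over the list alone (median -0.52, -0.52 with bounds, adjusted p = 0.130). In total 275 genes were higher and 187 lower, and 453 were called without pancreas 3 and intestine 3. Without background correction 445 were higher and 433 lower, and with receptor probes as negative controls 431 and 400. Without liver in the reference 531 genes were called with all arrays and 539 within the class of intensities over 20000.

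Intestinal endoderm was marked by Cdx2, the homeobox factor of intestinal identity, at least 50.9-fold higher than in the mean of the other organs (adjusted p = 2.3e-15, n = 3 against 16). Osr2 was at least 26.7-fold higher, Spink1 at least 14.3-fold, the intestine-specific homeobox gene Isx at least 10.9-fold and the bile acid transporter subunit Slc51a at least 11.3-fold. Of 11 tested members of the intestine list 7 were higher and 0 lower, also adjusted over the list alone, among them Lgals4 by 2.52 ± 0.16 and the brush border gene Vil1 at least 4.76-fold (median 1.98, 1.71 with bounds, adjusted p = 1.1e-07). Members not called were Hnf4a at 0.96 ± 0.19, Creb3l3 at -0.66 ± 0.07, Mttp at -0.42 ± 0.08 and Cdx1 at 0.26 ± 0.30.

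More posterior Hox genes were higher in intestine. In groups 5 to 8, 4 of 8 members were higher, Hoxb7 at least 5.21-fold and Hoxa7 at least 3.53-fold (median 1.21, 0.92 with bounds, adjusted p = 6.5e-05, adjusted p = 0.118 with an estimated correlation). In groups 9 to 13, 1 of 7 was higher, Hoxd10, at least 4.31-fold (median 0.62, 0.28 with bounds, adjusted p = 4.3e-04). Among groups 1 to 4, Hoxd4 was at least 7.55-fold higher, with 2 of 9 members called (median 0.07, 0.00 with bounds, adjusted p = 0.0771). The Hedgehog ligands Shh and Ihh were at least 9.06-fold and at least 4.15-fold higher, while their list had a median of -0.02, 0.00 with bounds, a mean of 0.76 and a test pointing higher, adjusted p = 0.154. Notch genes had 2 of 12 members lower, Nrarp at -2.09 ± 0.13 and Notch1 at -1.80 ± 0.21 (median -0.39, -0.28 with bounds, adjusted p = 0.00108). Secreted liver proteins were also higher, Serpina1b by 3.22 ± 0.20 and Apoa1 by 2.41 ± 0.17, in a hepatocyte list with 6 of 23 members higher and 6 lower and a median of -0.03, 0.00 with bounds, a mean of 0.22 and a test pointing lower, adjusted p = 0.912. Glycolysis genes had 2 of 16 higher, the glucose transporter Slc2a3 by 2.25 ± 0.29 and Hk2 by 1.23 ± 0.09 (median 0.21, 0.21 with bounds, adjusted p = 0.0432, adjusted p = 0.273 with an estimated correlation).

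Red cell transcripts moved with the intestinal genes. Of the erythroid list 5 of 10 members were higher, Hba-a1 by 2.85 ± 0.65, Hbb-y by 2.73 ± 0.63 and Hba-x by 2.54 ± 0.48 (median 1.10, 1.10 with bounds, adjusted p = 0.0438, adjusted p = 0.530 with an estimated correlation). Hbb-y stood at 12.17 ± 0.62 in intestine, 11.34 ± 1.31 in liver, 9.16 ± 0.79 in stomach and 8.55 ± 0.64 in esophagus (log2 intensity, SD, n = 3 each). Leukocyte genes had 0 of 8 members called (median -0.54, 0.00 with bounds, adjusted p = 0.00149, adjusted p = 0.117 with an estimated correlation). Liver, where leukocyte genes were higher, is part of the reference and raises it. The negative median therefore need not mean a lower level than in the organs other than liver. The intestine comparison called 263 genes higher and 104 lower, or 403 in all without pancreas 3 and intestine 3. Without background correction 450 were higher and 277 lower, and with receptor probes as negative controls 434 and 247. Without liver in the reference 374 genes were called with all arrays and 387 within the class of intensities over 20000.

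**Figure D5:**
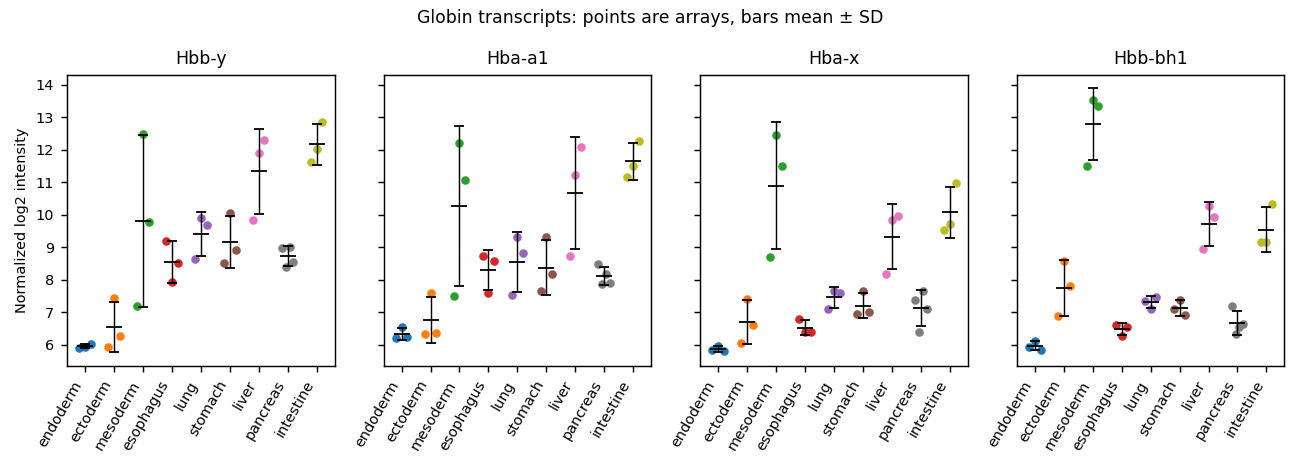
Normalized log2 intensity of 4 globin genes on the 28 arrays, grouped by sample. Hbb-y averaged 12.17 in intestine, 11.34 in liver and 5.97 in E8.25 endoderm, and its values differed between replicate arrays of liver and mesoderm.

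Genes higher in 1 organ than in each of the other 5, each pair tested on its own, numbered 368 in liver, 152 in esophagus, 117 in pancreas, 72 in intestine, 54 in lung and 19 in stomach. These counts include markers of other cell types and were not split by cell type. The liver genes included the blood cell markers Pf4, Laptm5, Mpo and C1qb and the endothelial gene Plvap. The esophagus genes included the mesenchyme markers Dcn and Acta2. The largest fitted margins over the next organ were those of Gcg in pancreas, 7.62, Apoa2 in liver, 7.51, Cdx2 in intestine, 5.42, Krt17 in esophagus, 5.34, Nkx2-1 in lung, 4.89, and Id4 in stomach, 2.22, all on the log2 scale. Genes lower than in each other organ numbered 232 in liver and 0 in stomach. Pairs of organs differed by 340 genes between lung and stomach, the lowest count of the 15 pairs, and by 1699 between esophagus and liver, the highest.

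Between E8.25 endoderm and the mean of the 6 organs at E11.5, genes of the early embryo were lower at the later stage. The forebrain and anterior endoderm factor Otx2 was at least 17.0-fold lower at E11.5 (adjusted p = 6.5e-17, n = 19 against 3 arrays), the RNA-binding protein Lin28a at least 13.9-fold, Gbx2 at least 13.9-fold and the carbonic anhydrase Car4 at least 23.0-fold. The inhibitor gene Spink1 and the hormone gene Trh were at least 20.2-fold and at least 14.3-fold lower. Of the pluripotency and early embryo list 5 of 14 members were lower and 0 higher, the methyltransferase Dnmt3b at -2.93 ± 0.11 and Sall4 at -2.35 ± 0.16 (median -0.63, -0.50 with bounds, adjusted p = 4.1e-05, adjusted p = 0.0515 with an estimated correlation). The definitive endoderm list had 6 of 18 lower and 2 higher (median -0.23, -0.19 with bounds, adjusted p = 0.130).

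Signalling and metabolic genes differed between E8.25 endoderm and the E11.5 organs. Of the BMP list 5 of 9 members were lower and 1 higher, Msx1 at least 13.2-fold and Bmp4 at least 4.52-fold lower (median -1.18, -0.97 with bounds, adjusted p = 8.4e-04). Wnt response genes had 3 of 11 lower, Axin2 at -2.31 ± 0.10 and Sp5 at -2.30 ± 0.22 (median -0.56, -0.27 with bounds, adjusted p = 0.00966, adjusted p = 0.117 with an estimated correlation). Glycolysis genes had 4 of 16 lower, the glucose transporters Slc2a3 and Slc2a1 at -4.24 ± 0.28 and -3.07 ± 0.19 and Ldha at -1.24 ± 0.15 (median -0.70, -0.59 with bounds, adjusted p = 2.4e-06). Cholesterol synthesis genes had 3 of 14 higher, Insig1 by 1.41 ± 0.14 and Hmgcs1 by 1.16 ± 0.14 (median 0.73, 0.73 with bounds, adjusted p = 1.3e-05, adjusted p = 0.0515 with an estimated correlation). Hox genes of groups 5 to 8 had 3 of 8 lower, Hoxa7 at least 8.08-fold (median -0.80, -0.53 with bounds, adjusted p = 0.0157, adjusted p = 0.353 with an estimated correlation). Imprinted genes went both ways, Phlda2 at -4.06 ± 0.21, Mest at -2.62 ± 0.23 and Dlk1 at 1.74 ± 0.20, with 3 of 11 higher and 2 lower and a median of 0.11, 0.11 with bounds, a mean of -0.18 and a test pointing higher, adjusted p = 0.831. The cell cycle list had 1 of 21 members higher and 0 lower, Tyms, at 1.36 ± 0.24, for which 2 of 4 other detected probes had the opposite sign, while the test put the list lower (median -0.48, -0.48 with bounds, adjusted p = 0.0154, adjusted p = 0.0845 with an estimated correlation). Adjusted over the list alone, the counts of the stage comparison were the same.

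Among genes higher at E11.5 the globins Hbb-y and Hba-a1 led, the former at least 11.9-fold and the latter by 2.94 ± 0.64, with 4 of 10 erythroid genes higher (median 0.64, 0.51 with bounds, adjusted p = 0.0117, adjusted p = 0.430 with an estimated correlation). The corepressor gene Tle5 was higher by 2.52 ± 0.13, the detoxifying enzyme Gstp1 by 2.44 ± 0.31, and Nfib by 2.14 ± 0.21. Also higher were Pfn1, by 2.07 ± 0.26, Rps6, by 2.05 ± 0.27, Atp5pb by 2.14 ± 0.30 and Hnrnpa2b1 by 2.38 ± 0.49. Rbm3, higher by 2.30 ± 0.32, had 2 other detected probes, and both had the opposite sign. The model called 330 genes higher and 335 lower, and the 5 organs other than liver gave 672 calls with all arrays and 710 within the class of intensities over 20000.

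Lung and esophagus, neighbours in the anterior foregut, were compared directly. Nkx2-1 was higher in lung by 4.89 ± 0.23 (adjusted p = 1.3e-13, n = 3 against 3), Wnt7b by 4.45 ± 0.30, Mia by 4.10 ± 0.37 and Etv5 by 3.78 ± 0.20. Esophagus had the higher levels of Krt17, at -5.34 ± 0.22, Krt15, at -5.33 ± 0.24, Trp63, at -4.49 ± 0.29, and the interferon-induced gene Ifitm3, at -4.20 ± 0.27. Of the esophagus list 11 of 12 members were lower in lung (median -2.36, -2.21 with bounds, adjusted p = 2.9e-21), and of the lung list 10 of 18 were higher and 2 lower (median 1.49, 1.31 with bounds, adjusted p = 2.8e-10). The Notch list had 4 of 12 lower in lung, Nrarp at -2.11 ± 0.17 (median -0.40, -0.40 with bounds, adjusted p = 4.4e-04). Hox groups 1 to 4 had 5 of 9 lower, Hoxb4 at -2.12 ± 0.25 (median -1.08, -1.08 with bounds, adjusted p = 4.0e-04, adjusted p = 0.0900 with an estimated correlation). Imprinted growth genes had 4 of 11 higher in lung, Dlk1 by 2.57 ± 0.27 (median 0.57, 0.57 with bounds, adjusted p = 0.00538). Cell cycle genes had 2 of 21 higher, Rrm2 by 1.16 ± 0.12 (median 0.40, 0.40 with bounds, adjusted p = 0.00118). Mesenchyme markers had 7 of 18 members lower in lung and 1 higher, Dcn at -3.53 ± 0.29 and Pdgfra at -1.30 ± 0.23 (median -0.35, -0.22 with bounds, adjusted p = 2.0e-04, adjusted p = 0.199 with an estimated correlation). Each count was also that adjusted over the list alone. The pair gave 218 genes higher and 369 lower, 587 in all, against 773 without lung 1 and 810 within the class of intensities over 20000, where lung keeps 2 arrays.

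Pancreas and intestine, neighbours around the duodenum, differed by 292 genes higher in pancreas and 344 lower. Gcg and Pyy were at least 247-fold and at least 131-fold higher in pancreas (adjusted p = 6.1e-18 and 3.2e-20, n = 4 against 3), Cpa1 at least 68.8-fold and Slc38a5 by 7.08 ± 0.29. Shh and Osr2 were at least 67.3-fold and at least 37.2-fold lower, and Cdx2 lower, at -5.42 ± 0.28. The endocrine list had 13 of 15 members higher (median 3.17, 2.78 with bounds, adjusted p = 1.1e-26), the progenitor list 9 of 16 (median 1.25, 1.04 with bounds, adjusted p = 3.2e-15) and the intestine list 7 of 11 lower (median -1.79, -1.41 with bounds, adjusted p = 5.0e-08). Notch genes had 6 of 12 members higher, Nrarp by 3.61 ± 0.16 and Notch1 by 2.44 ± 0.26 (median 0.73, 0.48 with bounds, adjusted p = 6.9e-06). Hox genes were lower, 6 of 8 in groups 5 to 8, Hoxb7 at -2.46 ± 0.17 (median -1.80, -1.41 with bounds, adjusted p = 1.2e-06, adjusted p = 0.0582 with an estimated correlation). In groups 1 to 4 there were 4 of 9, Hoxd4 at -3.22 ± 0.22 (median -0.78, -0.78 with bounds, adjusted p = 1.1e-04, adjusted p = 0.0635 with an estimated correlation). Glycolysis genes had 3 of 16 lower, Slc2a3 at -3.85 ± 0.35 (median -0.20, -0.20 with bounds, adjusted p = 0.00436, adjusted p = 0.115 with an estimated correlation). Globins moved with the intestinal genes, Hba-a1 at -3.53 ± 0.78 and Hbb-y at -3.43 ± 0.76, with 4 of 10 erythroid genes lower, or 5 adjusted over the list alone (median -1.11, -1.11 with bounds, adjusted p = 0.0103, adjusted p = 0.425 with an estimated correlation). Other counts of this pair were unchanged when adjusted over the list alone. The 7 arrays lie in 1 intensity class, and arrays of that class alone gave 643 genes.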

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

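Chosen only after the result was seen were the tests of a technical difference shared by 2 arrays, of blood cells, of array background and of the effect of lung 1 and stomach 1 on the stage comparison, whereas the tests of a swap, of embryo age and of probes within a gene were written before.

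Groups of 4 arrays were searched for an array far from the others, which only pancreas allows, and 2 of 22 pancreas values lay beyond Dixon's critical value. Chance flags about 1 in 20 groups. The gene Cltrn stood at 10.55 on pancreas 1 and between 11.27 and 11.41 on the other 3 arrays, with a gap of 0.840 of the range. The receptor threshold, a measure of array background, was 153 on pancreas 3 and between 25.5 and 36.7 on the others, with a gap of 0.912 of the range.

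Lung 1 and stomach 1 deviated alike from the other arrays of their organs, and lung 1 was about as close to stomach 1 (r = 0.9660) as to its closest lung array (r = 0.9658). A swap of the 2 arrays is excluded, since 94.9% of the 78 genes that separate lung from stomach lay on the side of each array's own label. The shared deviation correlated at -0.061 with the difference of esophagus, pancreas and intestine from E8.25 endoderm. A small difference in embryo age between lung or stomach pools at E11.5 need not follow that difference, so the test cannot decide on embryo age. The deviations of the 2 arrays from their organs correlated at 0.879, with 308 genes at least 1 log2 unit higher and 27 lower in both, but this restates the pattern, since any shared difference would give it. A technical difference shared by the 2 arrays therefore cannot be told apart from a biological one.

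Erythroid transcripts were higher in E11.5 intestine and liver. Array background cannot be told apart for the list as a whole: over its 10 members in these organs the level lay a median of 2.50 log2 units above the lowest detected one, between the bounds set for either answer. The 12 calls lay a median of 3.52 above it, with the lowest array value at 0.751, but their selection favours high levels. The median SD of the 10 erythroid genes between arrays of a group was 0.452, against 0.196 for the median of 10000 matched random lists and 0.258 for their 95th percentile, so the erythroid genes stood at percentile 100. This spread was pooled over all 9 groups, E8.25 mesoderm among them, where Hbb-y stood at 7.19, 12.48 and 9.76. It is therefore not a spread between organ pools alone and cannot decide whether the sorted organ fractions held blood cells in differing amounts. Expression by the sorted cells themselves was not tested.

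In the stage comparison 330 genes were higher at E11.5 than in E8.25 endoderm, and some of them, such as Rbm3, had other probes of opposite sign. With lung 1 and stomach 1 left out, 317 of the 330 genes, 96.1%, were still called higher. These calls therefore did not need the 2 arrays. But the 2 arrays carry little weight in the E11.5 mean, so most calls would stay whatever set them apart. The liver arrays, of the same intensity class, also stayed in the fit. The test therefore cannot decide whether the difference that set lung 1 and stomach 1 apart contributed. Probes that disagree within a gene cannot be told apart from a change of the gene, since 10% of 90 higher genes and 12.0% of 92 lower genes had another detected probe of opposite sign, and single probes may respond to different transcripts. The stage difference itself stays open, because E8.25 endoderm has 3 arrays and no organ was sampled at both stages.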

How the results depend on the processing

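The tests chosen after the files were seen are neqc with receptor probes, detection at the 95th percentile, leaving out pairs of arrays, and the intensity class as a block or within 1 class. Signal over background limits the calls of dim genes. Without background correction, which drops both the normexp step and its offset, and with neqc, every total count of calls was over 1.5 times higher, and which step raised it was not tested. In the order endoderm, ectoderm, mesoderm, esophagus, lung, stomach, liver, pancreas, intestine, stage, lung against esophagus and pancreas against intestine, counts without background correction were 747, 450, 1247, 1135, 722, 549, 2153, 878, 727, 1328, 984 and 983 (main analysis 362, 202, 604, 624, 364, 261, 1299, 462, 367, 665, 587 and 636). With neqc they were 711, 444, 1189, 1063, 669, 517, 2072, 831, 681, 1242, 949 and 972. Organ-restricted genes moved to 29 in stomach and 109 in intestine without background correction, and to 29 and 112 with neqc (main 19 and 72). Requiring detection on 14 of 28 arrays left 32 in lung, 200 in liver, 67 in pancreas and 41 in intestine, since fewer genes were tested (main 54, 368, 117 and 72).

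No other alternative, and no single array left out, moved a total count of a comparison by over 1.5 times. Of the counts by direction, lower genes in mesoderm went from 207 to 412 with the intensity class as a block, and with detection on 14 arrays higher genes went from 642 to 427 in liver and from 83 to 53 in ectoderm. Leaving out 1 array in turn, the count of lung against esophagus lay between 543 and 773. Of 711 named gene results, 711 kept direction and side of the threshold with an intensity trend and robust prior, 708 with every detected probe, 700 without detection filter, 698 with neqc, 696 without background correction, 693 with a median shift, 691 with array weights, whose estimation did not reach its convergence tolerance, and 686 with the intensity class as a block. Of 284 list results 216 kept their side of the threshold with an estimated correlation and 202 with fry. Counted over all fits that left out 1 array, 219 named gene results lost their call, 4 gained one and 10831 stayed. Among list results 52 lost their call, 28 gained one and 4289 stayed. Several lists close to the threshold lost their call under more than 1 alternative, among them neural ectoderm in endoderm, surface ectoderm in ectoderm, stomach in esophagus and erythroid and glycolysis in intestine.

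Signs turned in 8 results, and the cause was not tested. With detection on 14 arrays these were the pancreatic progenitor list in lung, -0.10 (adjusted p = 0.961), and the hepatocyte list in intestine, 0.75, which passed the threshold at adjusted p = 0.0451. With the intensity class as a block they were Pcna, -0.98 (adjusted p = 0.0137, short of a 2-fold change), and Hmga2, -0.42 (0.258), in mesoderm, and Hoxa5 in liver, 0.0269 (0.961). With fry the test direction turned for the stomach list in lung (median -0.38, adjusted p = 6.4e-04), imprinted genes in the stage comparison (0.11, 0.00422) and the lung list between pancreas and intestine (0.0237, 0.00553), all past the threshold.

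The replicate number as a block gave 364, 202, 609, 631, 358, 261, 1316, 460, 363, 660, 595 and 635 calls, and 153 restricted genes in esophagus, 55 in lung, 20 in stomach, 365 in liver, 114 in pancreas and 73 in intestine. In the comparisons treated as paired, of ectoderm and of pancreas against intestine, the block ended the calls of Etv4 (1.15 to 0.91), Rbp4 (1.07 to 0.92) and Egr1 (-2.03 to -1.84) in the latter and of the surface ectoderm list in the former, and of no other named gene or list there. Over all comparisons 10 named gene results and 4 list results lost their call with the block, and 1 list result gained one. The labels give no pairing. At E8.25, 8 of 9 pairs of arrays with the same number correlated over 0.1 (lowest 0.080, highest 0.402) and 9 of 9 arrays were closest to their own number, and at E11.5 25 of 45 pairs did (lowest -0.257, highest 0.879) and 13 of 19 arrays were. The chip as a random block was not run, as the chip of each sample is not given in the sources used here. The median shift and the normalization within each stage were run on normexp values in place of neqc.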

Other observations

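Chosen only after the result was seen were the test of the intensity class and the splits within replicate numbers, whereas the other splits were planned before the data were examined. Levels along the gut are given here as mean log2 intensity ± SD (n = 3, pancreas 4). Cdx2, the intestinal factor at E11.5, was present in all E8.25 layers, at 10.54 ± 0.21 in endoderm, 10.61 ± 0.66 in ectoderm and 9.61 ± 0.33 in mesoderm, against 12.12 ± 0.13 in intestine and 6.51 ± 0.07 in stomach. Pdx1 stood at 10.47 ± 0.52 in pancreas and 8.35 ± 0.25 in stomach and was detected on 0 of 3 endoderm arrays at E8.25. Sox2 stood at 9.39 ± 0.49 in esophagus, 8.55 ± 0.07 in stomach and 7.54 ± 0.35 in lung, and was detected on 0 arrays of liver, pancreas and intestine. Shh stood at 12.68 ± 0.33 in intestine, 12.03 ± 0.15 in esophagus, 11.30 ± 0.29 in lung and 11.20 ± 0.34 in stomach, and was detected on 0 arrays of liver and pancreas. Sox17, an endoderm factor at E8.25 with 8.88 ± 0.43 in endoderm and 8.13 ± 0.25 in mesoderm, was detected on 0 arrays of the 6 organs. Hnf4a stood at 11.02 ± 0.74 in liver, 9.22 ± 0.41 in intestine, 9.17 ± 0.18 in stomach and 8.47 ± 0.34 in pancreas.

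Each count was set against other splits of the same arrays into groups of the same sizes, 100 drawn at random where there were more. The median count of the other splits was 0 in every comparison, since mixed groups carry the differences between groups into the spread. A share under 0.05 therefore speaks against a random grouping of all the arrays compared. It does not exclude chance for the count of 1 layer or organ. For endoderm 2 of 100 splits gave as many genes as the real 362 (the real one included, highest other 600, the 3 mesoderm arrays), and for mesoderm 1 of 100 (real 604, highest other 110). Arrays of the same replicate number deviated together at E8.25, and splits that kept them in different groups gave 3 of 100 for endoderm (highest other 601) and 1 of 100 for mesoderm (highest other 601). The split with 601 genes set the 3 mesoderm arrays apart in both cases. Against mesoderm it only regrouped the reference arrays, so 604 and 601 come from nearly the same grouping. For ectoderm, whose 6 pairs with the other layers correlated at 0.264 or more, 9 of 100 such splits gave as many genes (real 202, highest other 604). Of the 8 others, 4 set the 3 endoderm arrays apart and 4 the 3 mesoderm arrays. Both of these layers gave more genes than ectoderm, 362 and 604, so such splits were bound to rank above it. The share therefore cannot decide on chance for ectoderm. Splits that mixed layers in the target gave at most 163. Without regard to the numbers 2 of 100 splits gave as many as ectoderm. The share was also under 0.05 for esophagus (2 of 100, real 624, highest other 1197, a split that set the 3 liver arrays apart), lung (2 of 100, real 364, highest other 385, with 2 liver arrays and 1 lung array together), stomach (3 of 100, real 261, highest other 371, with 2 liver arrays), liver (1 of 100, real 1299, highest other 575), pancreas (1 of 100, real 462, highest other 324) and intestine (2 of 100, real 367, highest other 444, the 3 esophagus arrays). The stage comparison had a share under 0.05 too (1 of 100, real 665, highest other 460). Splits that keep replicate numbers apart were not run for these comparisons. Lung and stomach arrays of the same number correlated at 0.879, 0.691 and 0.635, so the splits for these organs may count arrays that are not independent. For pancreas against intestine, whose 3 pairs of the same number correlated at 0.560 or more, only 8 splits part all the pairs, too few for a share under 0.05 (real 636, highest other 386, or 460 among all 35 splits). Among all 35 splits 1, the real one, gave as many. Since some arrays of different numbers correlated as well, it stays open which set of splits applies. For lung against esophagus the 10 splits are too few for a share under 0.05 (real 587, highest other 0).

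The intensity class of the arrays was compared across organs that hold both classes, after the files were seen. With the class as a block, 364 genes were called higher and 33 lower in the class without intensities over 20000, and 1731 passed an adjusted p under 0.05. The class holds all mesoderm and liver arrays, 1 lung and 1 stomach array, so its effect is estimated from lung 1 and stomach 1 alone.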
